A study of Mus musculus with 18 samples.

How the data were processed

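Total RNA of whole mammary glands from virgin female mice, RonTK-/- or RonTK+/+, at 5, 6 or 7 weeks of age was hybridised to Affymetrix Mouse Genome arrays, per the labels' protocols. RNA was extracted with TriZol after a spin to remove fat, amplified for 1 round to aminoallyl-aRNA and labelled with biotin, per the labels' protocols. The 18 arrays form 6 groups of 3, one for each genotype and age, and groups were taken from the labels of each array.

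The deposited values are linear ratios. This was found from the values, since the labels name no unit. All 811818 values are positive, each array has a median ratio of 1, and 87.37% of the 45101 probe sets have a median within 1e-04 of 1 over the 9 RonTK+/+ arrays, against 0.173% over the 9 RonTK-/- arrays and 0.612% over all 18. Most of the deposited values thus read as ratios to a RonTK+/+ median, and how the other probe sets were scaled is not given in the sources used here. The lowest ratio in the table is 0.01, shared by 103 values, and the highest is 122.6. The probe set summary, the background correction and the software are not given in the sources used here. The absolute level of each probe set cannot be recovered, so signal over background is unknown, no probe set was left out as dim, and no level of a gene was set against that of another gene. Scan dates and other batch labels are not given in the sources used here.

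Tests ran on log2 of the ratio, with no pseudocount. A log2 of the value plus 16 had been planned for linear intensities and is not suited to ratios. After 64 control probe sets were left out, 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none or were not listed in the platform annotation. Of those with 1 symbol, 34741 were matched through their Entrez gene to a RefSeq table (assembly GRCm38.p6), which changed 0 symbols. The table was used only for names, chromosomes and the order of neighbouring genes, because the files name no genome build. A gene's value is the mean of the log2 ratios of its probe sets with 1 symbol, the rule set for centred values, which gave 18193 genes.

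Analyses used R 4.3.3 with limma 3.58.1 and data.table (1.17.8), and figures used Python 3.11.15 with matplotlib 3.10.9. A linear model with 1 mean for each of the 6 groups was fitted to all 18 arrays with limma (lmFit and eBayes, 12 residual and 1.94 prior degrees of freedom), so that all groups share an estimate of the spread. RonTK-/- minus RonTK+/+ was tested as the mean over the 3 ages and at each age with the moderated t statistic of limma. The genotype by age interaction and the change with age in each genotype were tested with its moderated F statistic, with the direction of an age change from 7 minus 5 weeks. P-values are two-sided and were adjusted by Benjamini-Hochberg over all genes, and a gene was called at an adjusted p under 0.05.

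There were 41 gene lists, 15 for cell types a gland sample could hold and 26 for processes. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 41 lists of a comparison. Beside it stand camera with an estimated correlation, fry, and limma on the mean of each list per array, which takes the array as the unit. The PValue of fry tests whether a list's genes move on balance in the same direction, and its PValue.Mixed whether they change in either direction, and neither compares a list with other genes. Adjusted p-values called fry below come from PValue. The share of called genes within 20 Mb of Mst1r was compared with that among all other placed genes by Fisher's exact test, two-sided.

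The genes named were set by rule. Mst1r and Mst1 come first, followed by up to 10 genes with the largest rise and 10 with the largest fall among called genes. For genotype at a single age, every array of a genotype had to lie apart from every array of the other, and for the mean over ages the sign had to agree at all 3. Where under 5 genes passed, the 5 with the smallest p are named as not passing. Predicted and RIKEN genes are outside the rule, and those named here were named after their values were seen. From each list described, up to 4 members with the smallest p are named. The design, the gene lists, the naming rule and most of the alternatives were chosen before the data were examined.

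Alternatives covered quantile normalization, median centring, array weights, the replicate number as a block, the leading component of the residuals as a covariate, the means of the luminal epithelium, B lymphocyte or skeletal muscle lists as covariates, leaving out arrays, every probe set tested alone, other thresholds, and only the groups compared. The same code was tested on simulated data for 18193 genes with the residual spread of each gene, 50 genes changed at each fold size, and no correlation between genes. For genotype over the 3 ages it recovered 76% of genes changed 1.5-fold and 98% of those changed 2-fold, with 7 false calls beside 184 true ones. For genotype at 7 weeks it recovered 58% at 1.5-fold and 88% at 2-fold, and for the interaction 36% and 82%. In the arrays themselves 68.8% of the residual variance lay on the leading component, so these rates need not hold for them.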

Results

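Ron, encoded by Mst1r, is a receptor tyrosine kinase whose ligand, macrophage-stimulating protein, is encoded by Mst1. Transcripts of whole mammary glands were compared between virgin female mice without the tyrosine kinase domain of Ron (RonTK-/-) and RonTK+/+ controls at 5, 6 and 7 weeks of age. Each of the 6 groups held 3 arrays, and the labels do not state whether the 3 came from separate animals. A log2 ratio of 0 stands for the RonTK+/+ median in 87.37% of probe sets. The SD of the log2 ratios over the probe sets of an array ran from 0.125 in RonTK+/+ array 1 at 5 weeks to 0.45 in RonTK-/- array 2 at 7 weeks. The number of arrays limits the precision.

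Mst1r was measured by a single probe set, and no RonTK-/- array stood apart by a loss of its signal. At 5 weeks its ratios were 0.975, 0.857 and 1.06 in RonTK+/+ arrays and 0.87, 0.74 and 1.16 in RonTK-/- arrays. At 6 weeks they were 1.16, 1 and 1.13 against 1.56, 1.41 and 1.32, and at 7 weeks 0.808, 0.857 and 1.4 against 1.22, 2.1 and 1.3. Mean ratios ± SD (n = 3) were 0.963 ± 0.101 and 0.924 ± 0.216 at 5 weeks, 1.1 ± 0.0861 and 1.43 ± 0.124 at 6 weeks, and 1.02 ± 0.33 and 1.54 ± 0.486 at 7 weeks, RonTK+/+ first. The Mst1r difference over the 3 ages was 0.30 ± 0.13 (SE, limma adjusted p = 1), and that at 7 weeks was 0.60 ± 0.23 (adjusted p = 0.445). Without RonTK+/+ array 3 at 7 weeks, the Mst1r difference at 7 weeks was 0.85 and passed (adjusted p = 0.0404). That array held the highest RonTK+/+ ratio (1.4), so leaving it out enlarges the difference by construction. Mst1r passed at 7 weeks in no other of the 18 fits without 1 array. Whether the probe set lies inside the deleted part is not given in the sources used here, so it does not check the labels. Mst1 differed by -0.11 ± 0.05 over the 3 ages (adjusted p = 1).

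Transcripts of skeletal muscle and of lymphocytes differed between arrays of the same group, by up to 5.87 log2 units for the skeletal muscle list. The mean log2 ratio of 22 skeletal muscle genes was -3.46 or lower in 8 arrays, namely RonTK+/+ array 2 at every age, RonTK+/+ array 3 at 6 weeks, RonTK-/- array 3 at 5 weeks and all 3 RonTK-/- arrays at 6 weeks. It lay between 0.00 and 0.80 in the other 10 arrays, all 3 RonTK-/- arrays at 7 weeks among them. The mean of 16 B lymphocyte genes was -2.15 or lower in 8 of those 10, and that of 15 T lymphocyte genes was -2.47 or lower in the same 8. RonTK+/+ array 1 and RonTK-/- array 1 at 5 weeks held both muscle and lymphocyte transcripts. Epidermis and hair genes (19 measured) were raised in RonTK-/- array 1 at 6 weeks (2.00), RonTK+/+ array 3 at 5 weeks (1.16) and RonTK+/+ array 1 at 6 weeks (1.14). The muscle mean per group was -1.65, -2.61 and -1.42 in RonTK+/+ and -1.23, -4.61 and 0.29 in RonTK-/- at 5, 6 and 7 weeks.

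**Figure D1:**
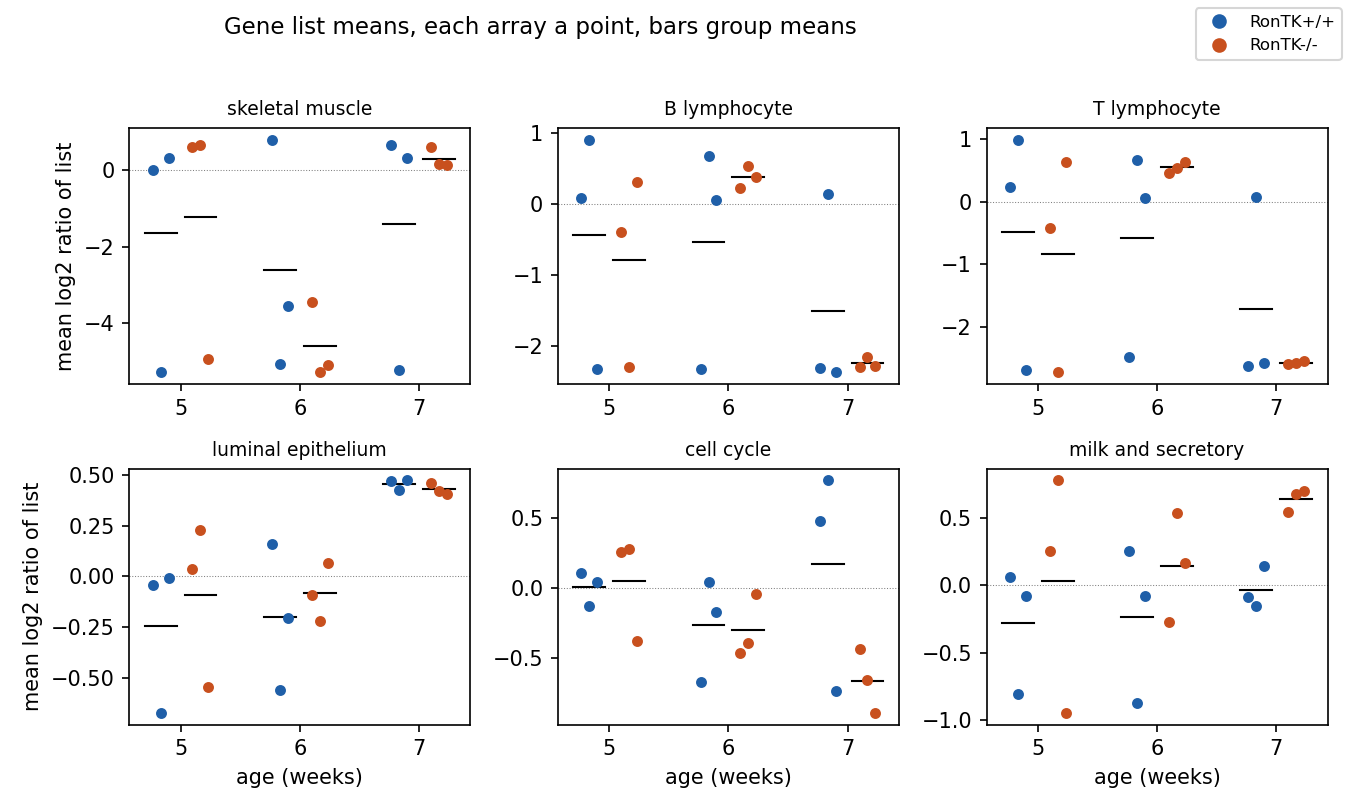
Mean log2 ratio of 6 gene lists (vertical axes) by age in weeks, with each array as a point, RonTK+/+ in blue, RonTK-/- in orange and group means as bars. The skeletal muscle list sits at -3.46 or lower in 8 arrays and between 0.00 and 0.80 in the other 10.

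Over the 3 ages, 11 of 18193 genes differed between genotypes, 4 higher and 7 lower in RonTK-/- glands. The largest fall was in Zfp949, a zinc finger gene, at -2.20 ± 0.09 (SE, n = 9 against 9, adjusted p = 2.56e-08), or 4.59-fold. Pxylp1, a phosphatase of glycosaminoglycan synthesis, fell by 1.18 ± 0.06 (adjusted p = 2.02e-07), and Gsta4, a glutathione transferase for lipid aldehydes, fell by 0.88 ± 0.12 (adjusted p = 0.00713). Also lower were Cep162, a centriole and cilium gene (-0.79), the ubiquitin ligase gene Mid1 (-0.47), Srprb, a subunit of the signal recognition particle receptor (-0.45), and the adaptor gene Nck1 (-0.44). Their adjusted p ran from 9.35e-05 for Mid1 to 0.00214 for Srprb. The kinase gene Mapk6 rose by 0.32 ± 0.05 (adjusted p = 0.0164), as did the RIKEN genes C920006O11Rik (1.38 ± 0.09), 9330159M07Rik (0.92 ± 0.10) and 9430037G07Rik (0.57 ± 0.07). Each of the 11 had the same sign at every age. Both probe sets of Zfp949 fell by 2.20. All probe sets of Pxylp1 (-0.27 to -1.70), Cep162 (-0.30 to -1.52) and C920006O11Rik (0.51 to 2.24) moved in the same direction but by unlike amounts. Those of Srprb ran from -1.27 to 0.41 and a single probe set carried Nck1 (-1.25), Mid1 (-1.26) and Mapk6 (0.98).

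The test was limma with adjustment over all genes, and 686 genes had an unadjusted p under 0.05. The count was 1 after quantile normalization, 23 with array weights, 28 over single probe sets and 3 at a fold of at least 2. It was 3 in the arrays with muscle transcripts alone, 3 in those low in muscle and 41 without RonTK+/+ array 3 at 7 weeks. Mapk6 lost its call (adjusted p up to 0.0617) without RonTK-/- array 1 or 3 at 5 weeks, 1 or 3 at 7 weeks, or RonTK+/+ array 2 at 5 weeks, 1 or 2 at 6 weeks, or 1 at 7 weeks.

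**Figure D2:**
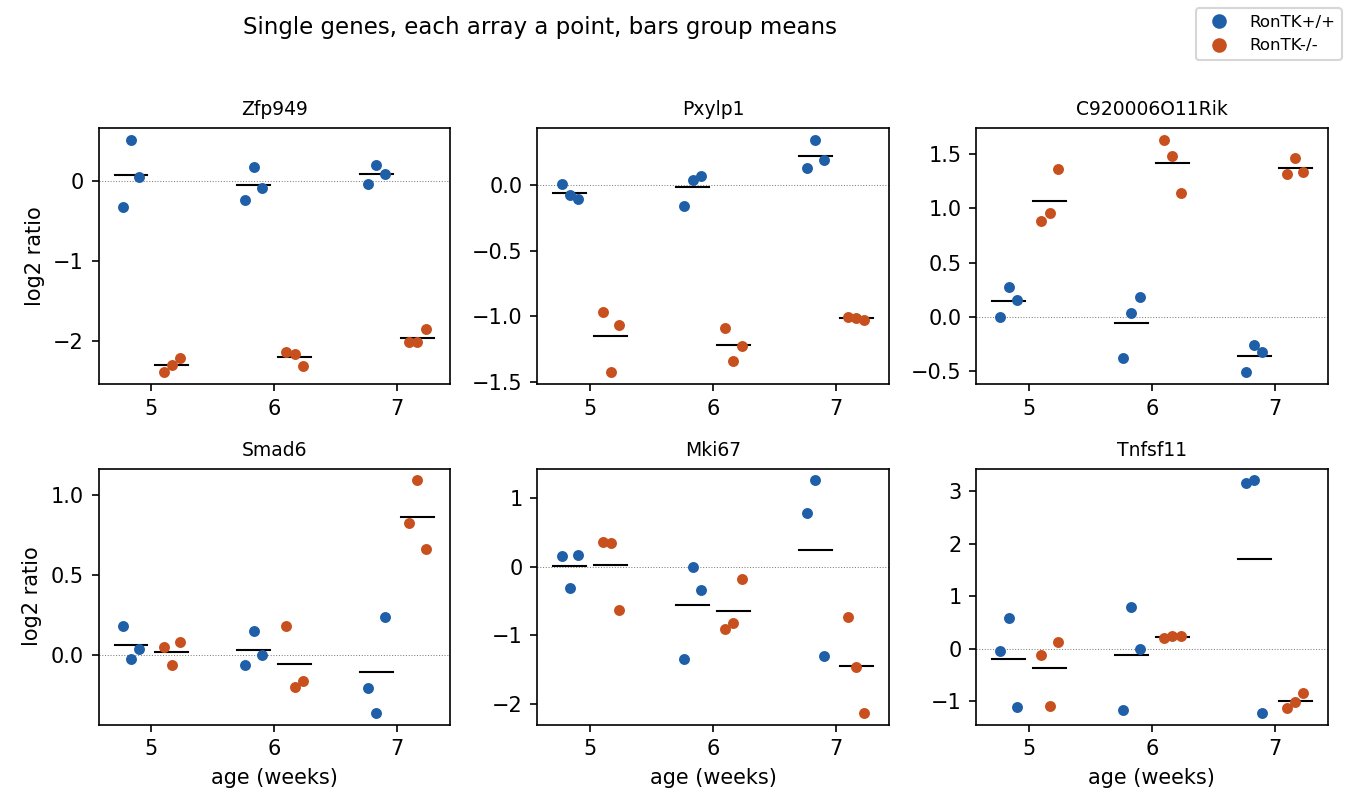
Log2 ratios (vertical axes) of 6 genes by age in weeks, with each array as a point, RonTK+/+ in blue, RonTK-/- in orange and group means as bars. Zfp949 lies between -2.39 and -1.85 in every RonTK-/- array, and Tnfsf11 reaches 3.17 and 3.21 in RonTK+/+ arrays 1 and 2 at 7 weeks against -1.23 in array 3.

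Of the 11 genes, 10 lay on chromosome 9, which also carries Mst1r, and Mid1 lay on X. In gene order (RefSeq, GRCm38.p6) all 10 preceded Mst1r, number 794 of the 1006 chromosome 9 genes tested. They ran from Mapk6 at 572, C920006O11Rik at 590 and Gsta4 at 591 through Cep162 at 636, Zfp949 at 642 and Pxylp1 at 683 to Nck1 at 712 and Srprb at 725. Within 20 Mb of Mst1r, 6 of 368 genes were called (1.63%), against 5 of 17776 other placed genes (0.0281%, Fisher's exact p = 2.83e-08, two-sided). Over the whole chromosome, 10 of 1005 other genes were called against 1 of 17139 elsewhere (Fisher's exact p = 2.72e-12). Within 5 Mb, 1 of 168 was called (Fisher's exact p = 0.0973), and after quantile normalization 0 were called within 20 Mb and 1 in all. The differences stayed after quantile normalization while the calls were lost, at -2.31 for Zfp949 (adjusted p = 0.129), -1.34 for Pxylp1 (adjusted p = 0.129) and -0.84 for Cep162 (adjusted p = 0.218).

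Among the gene lists, milk protein genes were higher in RonTK-/- glands relative to other genes over the 3 ages (adjusted p = 0.926 with an estimated correlation), while lower cell cycle genes came almost wholly from 7 weeks. Over the 3 ages all 30 cell cycle genes lay below 0 (mean -0.27 ± 0.19, SE), a fall relative to other genes (camera adjusted p = 3.87e-10) that was lost with the estimated correlation (adjusted p = 0.926 with an estimated correlation). The cell cycle difference was 0.05 at 5 weeks, -0.03 at 6 weeks and -0.83 at 7 weeks, and over the ages -0.17 without RonTK+/+ array 2 and -0.43 without array 3 at 7 weeks. Of 19 milk and secretory genes, 15 lay above 0 (mean 0.45 ± 0.23, camera adjusted p = 4.88e-05, adjusted p = 0.926 with an estimated correlation). The milk list difference was 0.30 at 5 weeks and 0.37 at 6 weeks, where it was not called, and 0.67 at 7 weeks. Of its genes, 2 rose adjusted over the list alone and 0 over all genes, Btn1a1, a milk fat globule protein gene (0.81 ± 0.19), and Lalba, encoding alpha-lactalbumin (1.39 ± 0.38). All 15 white adipocyte genes lay above 0 (mean 0.16 ± 0.11, camera adjusted p = 4.4e-04, adjusted p = 0.926 with an estimated correlation), but the difference was -0.08 at 5 weeks, 0.14 at 6 weeks and 0.42 at 7 weeks. It was 0.09 without RonTK-/- array 3 at 5 weeks, which ended the call (adjusted p = 0.0875), 0.11 without RonTK+/+ array 1 at 6 weeks and 0.10 without RonTK+/+ array 1 at 7 weeks. Of the 11 lists called, 3 had the same sign at every age, namely milk proteins, TGF-beta pathway and unfolded protein response. Macrophage (mean -0.09) and endothelial genes (mean 0.07) were also called without the same sign at every age, each with adjusted p = 0.958 with an estimated correlation. Their calls were lost in 7 and 9 of the 18 fits without 1 array. Of 41 lists, 11 were called with the preset correlation, 0 with the estimated correlation (smallest adjusted p = 0.594), 0 by fry and 0 on list means (smallest adjusted p = 0.686). The count was 19 without RonTK+/+ array 1 at 6 weeks, 7 without RonTK-/- array 3 at 5 weeks, 7 without RonTK-/- array 2 at 6 weeks and 6 without RonTK+/+ array 2 at 7 weeks.

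At 5 weeks, Zfp949 and Pxylp1 fell in RonTK-/- glands, Zfp949 by 2.39 ± 0.16 (SE, n = 3 against 3, adjusted p = 1.36e-05) and Pxylp1 by 1.10 ± 0.11 (adjusted p = 0.00066). The next genes did not pass. These were Mid1 (-0.45 ± 0.07, adjusted p = 0.108) and Nck1 (-0.46 ± 0.08, adjusted p = 0.147). Others were the urinary protein gene Mup10 (2.24 ± 0.39, adjusted p = 0.147), the macrophage lectin gene Lgals3 (-0.74 ± 0.14, adjusted p = 0.231) and the myeloid receptor gene Cd300lb (-1.03 ± 0.21, adjusted p = 0.392). Macrophage genes were lower in RonTK-/-, with 16 of 18 below 0 (mean -0.42 ± 0.20, camera adjusted p = 1.04e-10, adjusted p = 0.275 with an estimated correlation). Adjusted over the list alone, 7 of them fell and over all genes 0, among them Cd68 (-0.88 ± 0.22), Ms4a7 (-0.81 ± 0.20) and Adgre1 (-0.66 ± 0.19). All 23 interferon response genes lay below 0 (mean -0.43 ± 0.24, camera adjusted p = 2.83e-10, adjusted p = 0.467 with an estimated correlation). Lipogenesis (23 of 24 above 0, mean 0.38 ± 0.23, camera adjusted p = 1.78e-06) and sterol synthesis (16 of 17 above 0, mean 0.31 ± 0.17, camera adjusted p = 1.37e-06) rose relative to other genes. Lipogenesis had adjusted p = 0.664 with an estimated correlation and a mean of 0.25 without RonTK-/- array 3 at 5 weeks, and for sterol synthesis adjusted p = 0.604 with an estimated correlation. Beside these, brown adipocyte genes were called up (mean 0.63 ± 0.56, camera adjusted p = 0.0284) and epidermis (mean -0.38 ± 0.48, camera adjusted p = 0.0195) and fibroblast genes (mean -0.12 ± 0.13, camera adjusted p = 0.00502) down. Each had adjusted p = 0.742 with an estimated correlation. The brown adipocyte call was lost without RonTK+/+ array 2 (mean 0.09, adjusted p = 0.971) or RonTK-/- array 1 or 3 (adjusted p = 0.0766 and 0.148), and its mean was 0.999 without RonTK+/+ array 3. Without RonTK+/+ array 3 the epidermis mean was 0.02 (adjusted p = 0.691) and the fibroblast mean -0.01 (adjusted p = 0.729), and both calls were also lost without RonTK-/- array 3 (adjusted p = 0.0575 and 0.228). The epidermis mean was -0.58 without RonTK+/+ array 1 and -0.57 without array 2, and the fibroblast mean -0.20 without RonTK-/- array 2 and -0.21 without RonTK+/+ array 2.

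The limma count at 5 weeks was 2 genes, with 623 at an unadjusted p under 0.05. It was 0 after quantile normalization, 10 with array weights, 10 with the residual component, 8 with the B lymphocyte covariate, 6 with the skeletal muscle covariate, 13 over single probe sets and 0 with only the 5-week arrays. Of the 41 lists 15 were called, 4 up and 11 down, and 0 with the estimated correlation (smallest adjusted p = 0.156), by fry or on list means.

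At 6 weeks, Zfp949 fell by 2.16 ± 0.16 (SE, n = 3 against 3, adjusted p = 4.87e-05), Pxylp1 fell by 1.21 ± 0.11 (adjusted p = 0.000209) and C920006O11Rik rose by 1.47 ± 0.16 (adjusted p = 0.00168). Mid1 (-0.46 ± 0.07, adjusted p = 0.0795) and Mapk6 (0.45 ± 0.08, adjusted p = 0.324) did not pass. Nor did Sertad1 (0.46 ± 0.09, adjusted p = 0.361), Tbc1d8b (0.23 ± 0.04, adjusted p = 0.399) or Gsta4 (-1.02 ± 0.21, adjusted p = 0.457). All 23 interferon response genes lay above 0 (mean 0.49 ± 0.24, camera adjusted p = 1.2e-08, adjusted p = 0.992 with an estimated correlation). A single array carried most of this, as the interferon mean was 0.18 without RonTK-/- array 3 at 6 weeks (camera adjusted p = 0.0479), against 0.75 without RonTK-/- array 1. Immediate early genes were also called up (16 of 23 above 0, mean 0.23 ± 0.10, camera adjusted p = 0.00566, adjusted p = 0.992 with an estimated correlation). Of them 1 rose adjusted over the list alone and 0 over all genes, the chaperone gene Dnajb1 (0.47 ± 0.12). B lymphocyte (mean 0.91 ± 0.96) and T lymphocyte genes (mean 1.13 ± 1.09) were called up and skeletal muscle genes down (mean -2.001 ± 2.031). The camera adjusted p was 0.00557, 0.0019 and 0.0056, and each time adjusted p = 0.992 with an estimated correlation. These 3 calls were lost without RonTK+/+ array 1 at 6 weeks (adjusted p = 0.848, 0.394 and 0.937), the only array at 6 weeks with muscle transcripts. Without it the B lymphocyte mean was 0.02, the T lymphocyte mean 0.18 and the muscle mean -0.30, and without RonTK+/+ array 2 they were 1.52, 1.75 and -3.23.

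The limma count at 6 weeks was 3 genes, with 1119 at an unadjusted p under 0.05. It was 0 after quantile normalization, 8 with array weights, 346 with the residual component, 10 over single probe sets and 1 with only the 6-week arrays. Of the 41 lists 9 were called, and 0 with the estimated correlation, by fry or on list means (smallest adjusted p = 0.942).

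At 7 weeks, 6 genes differed between genotypes, and cell cycle genes were lower in RonTK-/- glands relative to other genes (adjusted p = 0.712 with an estimated correlation). Zfp949 fell by 2.05 ± 0.16 (SE, n = 3 against 3, adjusted p = 9.96e-05). Also lower were Pxylp1 (-1.24 ± 0.11), Cep162 (-1.11 ± 0.15, adjusted p = 0.0173) and Mid1 (-0.51 ± 0.07, adjusted p = 0.022). C920006O11Rik rose by 1.73 ± 0.16, and Smad6, an inhibitor of BMP signalling also on chromosome 9, rose by 0.97 ± 0.15 (adjusted p = 0.0401). All 30 cell cycle genes lay below 0 (mean -0.83 ± 0.32, camera adjusted p = 4.35e-20). Adjusted over the list alone, 17 of the 30 fell and over all genes 0. Among the 17 were the mitotic motor gene Kif11 (-1.07 ± 0.34), Nusap1 (-0.95 ± 0.30), the topoisomerase gene Top2a (-0.73 ± 0.24) and the spindle checkpoint gene Bub1b (-0.68 ± 0.22). The mean of all 30 was 0.48, 0.77 and -0.73 in RonTK+/+ arrays 1, 2 and 3 and -0.43, -0.66 and -0.89 in RonTK-/- arrays, so RonTK+/+ array 3 lay among the RonTK-/- values. Without that array, 886 genes were called, 353 higher and 533 lower in RonTK-/-, among them 27 of the 30 cell cycle genes. The cell cycle mean was then -1.29 (adjusted p = 0.517 with an estimated correlation), and it was -0.53 without RonTK+/+ array 2. Without RonTK-/- array 2 or 3 or RonTK+/+ array 1 or 2 at 7 weeks, 3 genes were called each time.

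White adipocyte genes (15 of 15 above 0, mean 0.42 ± 0.20, camera adjusted p = 5.26e-05) and endothelial genes (15 of 15 above 0, mean 0.28 ± 0.12, camera adjusted p = 5.26e-05) rose relative to other genes at 7 weeks. For each it was adjusted p = 0.756 with an estimated correlation, and the white adipocyte mean was 0.25 without RonTK+/+ array 1. Lists of B lymphocyte (mean -0.73 ± 0.96) and T lymphocyte genes (mean -0.86 ± 1.09) were called down (camera adjusted p = 0.0231 and 0.0178), each with adjusted p = 0.903 with an estimated correlation. A single array low in muscle carried both, as the B lymphocyte mean was 0.09 (adjusted p = 0.995) and the T lymphocyte mean 0.03 (adjusted p = 0.788) without RonTK+/+ array 2. Both calls were also lost without RonTK-/- array 1 (adjusted p = 0.0575 and 0.053), and that of B lymphocytes without RonTK-/- array 3 (adjusted p = 0.062). Without RonTK+/+ array 1 the means were -1.13 and -1.32, and without RonTK+/+ array 3 -1.16 and -1.29. Of 19 milk and secretory genes, 14 lay above 0 (mean 0.67 ± 0.39, camera adjusted p = 0.0056, adjusted p = 0.804 with an estimated correlation). Adjusted over the list alone, 6 rose and over all genes 0, among them Lalba (3.13 ± 0.65), Btn1a1 (1.31 ± 0.34), Mfge8 (0.46 ± 0.14) and Muc1 (0.55 ± 0.18). Matrix proteases and their inhibitors were higher (12 of 16 above 0, mean 0.33 ± 0.08, camera adjusted p = 0.0081, fry adjusted p = 0.0146, list mean adjusted p = 0.0522). It was adjusted p = 0.189 with an estimated correlation, and the camera call was lost without RonTK+/+ array 3 (adjusted p = 0.11). Of 21 TGF-beta pathway genes 15 lay above 0 (camera adjusted p = 0.0306, fry adjusted p = 0.0146, adjusted p = 0.329 with an estimated correlation). Of these 1, Smad6, rose over all genes, and Smad6, Fst (0.62 ± 0.13) and Bmp2 (0.78 ± 0.25) rose adjusted over the list alone. That camera call was lost without RonTK-/- array 1 or 3 or RonTK+/+ array 3 (adjusted p = 0.0967, 0.063 and 0.11).

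The limma test at 7 weeks had 1774 genes at an unadjusted p under 0.05. The count of 6 became 0 after quantile normalization, 546 with array weights and 85 with the residual component. It was 10 over single probe sets, 3 without the arrays raised in epidermis genes and 3 with only the 7-week arrays. Smad6 lost its call in 16 of the 18 fits without 1 array (adjusted p = 0.336 without RonTK-/- array 2 at 7 weeks), keeping it without RonTK-/- array 1 at 6 weeks or RonTK+/+ array 3 at 7 weeks. Cep162 lost its call without any of RonTK-/- arrays 1, 2 and 3 or RonTK+/+ arrays 1 and 2 at 7 weeks (adjusted p up to 0.15). Mid1 lost its call without the same arrays or RonTK-/- array 1 at 5 weeks (adjusted p up to 0.193). Of the 41 lists 10 were called, 6 without RonTK-/- array 1, 19 without RonTK-/- array 2 and 19 without RonTK+/+ array 1, and 0 with the estimated correlation.

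The genotype difference at 5, 6 and 7 weeks was compared by an interaction test. The genes with the smallest p did not pass, each with an adjusted p of 0.697. The difference of Cd300lb was 1.92 ± 0.30 (SE) larger at 7 than at 5 weeks, and that of Lgals3 1.15 ± 0.20. The same figure was 0.78 ± 0.13 for the macrophage transporter gene Slc37a2, 1.01 ± 0.21 for Smad6 and 0.70 ± 0.13 for Cd300a. Matrix proteases came nearest among the list means (unadjusted p = 0.00192, adjusted p = 0.0789). The moderated F of limma called 0 of 18193 genes, with 1240 at an unadjusted p under 0.05, and limma on list means called 0 of 41 lists. The count was 122 without RonTK+/+ array 3 at 7 weeks and 737 with the residual component.

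From 5 to 7 weeks, transcripts of luminal epithelium and sterol synthesis rose relative to other genes in RonTK+/+ glands (each adjusted p = 0.426 with an estimated correlation). All 19 genes that changed with age rose, led by Sqle, a squalene epoxidase (1.503 ± 0.212, SE, 7 minus 5 weeks), and the tight junction gene Tjp3 (1.42 ± 0.23). Gprasp2 (0.86), the fatty acid desaturase gene Fads2 (0.83), the ubiquitin ligase gene Rnf43 (0.73), Dlg3 (0.67), Stap2 (0.60), Lratd2 (0.59), the protease inhibitor gene Spint2 (0.59) and Colgalt2 (0.49) followed. Their adjusted p ran from 0.0293 for Sqle to 0.0483 for Stap2. All 21 luminal genes lay above 0 (mean 0.70 ± 0.21, camera adjusted p = 1.68e-14, adjusted p = 0.426 with an estimated correlation). Of them 13 rose adjusted over the list alone and 1, Spint2, over all genes. Cldn3 (1.01 ± 0.20), Kit (0.86 ± 0.17) and Esrp2 (0.76 ± 0.16) were among the 13. All 17 sterol synthesis genes lay above 0 (mean 0.66 ± 0.17, camera adjusted p = 2.1e-12, adjusted p = 0.426 with an estimated correlation). Of them 9 rose adjusted over the list alone and 2 over all genes in the contrast of 7 and 5 weeks, Sqle and Idi1 (1.28 ± 0.24). Of 24 lipogenesis genes, 10 rose and 1, Pck1 (-1.26 ± 0.33), fell adjusted over the list alone and 0 over all genes, with Acly at 1.03 ± 0.23 and Scd2 at 1.17 ± 0.27. The list mean was 0.63 ± 0.23 (camera adjusted p = 2.54e-07, adjusted p = 0.426 with an estimated correlation), and 0.34 without RonTK+/+ array 3 at 7 weeks (camera adjusted p = 0.0273). Basal and myoepithelial genes rose relative to other genes (mean 0.54 ± 0.20, camera adjusted p = 2.08e-06, adjusted p = 0.426 with an estimated correlation). Of 15, 6 rose adjusted over the list alone and 0 over all genes, led by the oxytocin receptor gene Oxtr (1.20 ± 0.23). Macrophage genes fell relative to other genes (17 of 18 below 0, mean -0.48 ± 0.20, camera adjusted p = 3.23e-08, adjusted p = 0.426 with an estimated correlation). Of them 3 fell adjusted over the list alone and 0 over all genes, Cd68 (-0.83 ± 0.23), Ms4a7 (-0.73 ± 0.20) and Cd163 (-1.11 ± 0.34). B lymphocyte (mean -1.07 ± 0.96, camera adjusted p = 3e-04) and T lymphocyte genes (mean -1.22 ± 1.09, camera adjusted p = 0.00121) were called down beside them, each with adjusted p = 0.687 with an estimated correlation. Both calls were lost without RonTK+/+ array 2 at 5 weeks (means -0.40 and -0.48, adjusted p = 0.0686 and 0.121) or array 3 at 7 weeks (means -0.64 and -0.79, adjusted p = 0.0973 and 0.119). The means were -2.02 and -2.32 without RonTK+/+ array 3 at 5 weeks, -0.68 and -0.76 without array 1 and -1.90 and -2.12 without array 2 at 7 weeks. White adipocyte (mean -0.27 ± 0.20, camera adjusted p = 0.0193), epidermis (mean -0.35 ± 0.48, camera adjusted p = 0.0243) and fibroblast genes (mean -0.11 ± 0.13, camera adjusted p = 0.0349) were called down too, each with adjusted p = 0.687 with an estimated correlation. All 3 calls were lost without RonTK+/+ array 3 at 5 weeks (adjusted p = 0.0987, 0.863 and 0.864). That of white adipocytes was also lost without RonTK+/+ array 1 at 7 weeks (adjusted p = 0.604), that of epidermis without array 2 or 3 (adjusted p = 0.0719 and 0.066) and that of fibroblasts without array 3 (adjusted p = 0.854). The white adipocyte mean was -0.10 without array 1 at 7 weeks. The epidermis mean was 0.04 without array 3 at 5 weeks, -0.56 without array 1 and -0.55 without array 2. The fibroblast mean was -0.004 and -0.20 without arrays 3 and 2 at 5 weeks, and 0.007 and -0.19 without arrays 3 and 2 at 7 weeks.

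The moderated F of limma had 1623 genes at an unadjusted p under 0.05 in RonTK+/+. Of 41 lists 17 were called with the preset and 0 with the estimated correlation, by fry or on list means (smallest adjusted p = 0.0888). The count of 19 was 0 without RonTK-/- array 1 at 5 weeks, RonTK-/- array 1 or 2 at 6 weeks, RonTK+/+ array 2 or 3 at 5 weeks, 2 or 3 at 6 weeks, or 1 or 2 at 7 weeks. It was 1 without RonTK-/- array 3 at 7 weeks, 63 without RonTK+/+ array 1 at 6 weeks and 350 without RonTK+/+ array 3 at 7 weeks. It was 2 after quantile normalization, 592 with array weights, 689 with the residual component, 0 with the luminal covariate and 0 with the replicate block. It was 192 with the skeletal muscle covariate, 62 with both tissue covariates, 3 without the arrays raised in epidermis genes, 0 over single probe sets and 0 with only the RonTK+/+ arrays.

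From 5 to 7 weeks, transcripts of matrix proteases and the Notch pathway rose in RonTK-/- glands, and those of luminal epithelium rose relative to other genes. The 3 lists had adjusted p = 0.149, 0.149 and 0.512 with an estimated correlation. Of 7 genes that changed, 6 rose. These were Clba1 (0.91 ± 0.13, SE), the cofilin phosphatase gene Ssh3 (0.74 ± 0.10), Zfp449 (0.56 ± 0.10), the Notch regulator gene Dtx4 (0.53 ± 0.07), Ildr1 (0.52 ± 0.07) and the kinase gene Mark1 (0.51 ± 0.07). Srp54b fell by 0.57 ± 0.08, and the adjusted p ran from 0.0301 for Mark1 to 0.041 for Clba1. Of 16 matrix protease genes 13 lay above 0 (mean 0.41 ± 0.08, list mean adjusted p = 0.00811, fry adjusted p = 0.00438, camera adjusted p = 0.00554, adjusted p = 0.149 with an estimated correlation). Of them 4 rose adjusted over the list alone and 1, Mmp3, over all genes in the contrast of 7 and 5 weeks. Mmp3, a stromal metalloprotease gene (1.88 ± 0.31), was not among the 7 genes called by the moderated F. It was followed by the gelatinase gene Mmp2 (0.80 ± 0.19). Of 15 Notch genes 14 lay above 0 (mean 0.27 ± 0.07, list mean adjusted p = 0.0179, fry adjusted p = 0.00438, camera adjusted p = 0.000125, adjusted p = 0.149 with an estimated correlation). Of them 0 were called adjusted over the list alone or over all genes. All 21 luminal genes lay above 0 (mean 0.52 ± 0.21, camera adjusted p = 5.59e-07, adjusted p = 0.512 with an estimated correlation). The luminal mean was 0.30 without RonTK-/- array 3 at 5 weeks, which was low in muscle (camera adjusted p = 0.00225). Of them 6 rose adjusted over the list alone and 0 over all genes, Cldn3 at 0.82 ± 0.20 and Spint2 at 0.40 ± 0.09 among them. Basal and myoepithelial genes were called up (mean 0.33 ± 0.20, camera adjusted p = 0.0128, adjusted p = 0.655 with an estimated correlation), a call lost without RonTK-/- array 3 at 5 weeks (mean 0.20, adjusted p = 0.123) or 7 weeks (adjusted p = 0.0712). All 30 cell cycle genes lay below 0 (mean -0.71 ± 0.32, camera adjusted p = 5.2e-13, adjusted p = 0.512 with an estimated correlation), with 0 down adjusted over the list alone or over all genes. Endothelial genes rose relative to other genes (15 of 15 above 0, mean 0.34 ± 0.12, camera adjusted p = 4.21e-05, adjusted p = 0.512 with an estimated correlation), with a mean of 0.22 without RonTK-/- array 2 at 5 weeks. So did mast cell genes (9 of 10 above 0, mean 0.48 ± 0.16, camera adjusted p = 0.000379, adjusted p = 0.512 with an estimated correlation). B lymphocyte (mean -1.46 ± 0.96, camera adjusted p = 2.51e-05) and T lymphocyte genes (mean -1.74 ± 1.09, camera adjusted p = 1.77e-05) were called down. For each it was adjusted p = 0.655 with an estimated correlation, and their means were -0.90 and -0.998 without RonTK-/- array 3 and -2.21 and -2.68 without RonTK-/- array 2 at 5 weeks. That array 2 already lay at -2.29 and -2.72, against -2.30 to -2.15 and -2.59 to -2.54 in the RonTK-/- arrays at 7 weeks. The difference thus follows which arrays at 5 weeks held lymphocyte transcripts, and an age change cannot be told apart from tissue content. Dtx4 and Ildr1 were called with age in both genotypes, against 0.00731 genes expected by chance (Fisher's exact p = 2.16e-05). Both tests share the residual spread of a gene, so they are not independent and nothing is drawn from that p-value.

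In RonTK-/- the moderated F of limma had 3192 genes at an unadjusted p under 0.05. Of 41 lists 12 were called with the preset correlation, 0 with the estimated correlation, 4 by fry and 4 on list means. The count of 7 was 0 without RonTK-/- array 3 at 5 weeks, 2 or 3 at 6 weeks, or 1, 2 or 3 at 7 weeks, or RonTK+/+ array 1 at 5 weeks or 3 at 6 weeks. It was 1 without RonTK-/- array 1 and 2 without RonTK-/- array 2 at 5 weeks, 3 without RonTK+/+ array 2 at 5 weeks, 17 without RonTK+/+ array 1 at 6 weeks and 30 without RonTK+/+ array 3 at 7 weeks. It was 2 after quantile normalization, 5356 with array weights, 3800 with the residual component and 11 with the skeletal muscle covariate. It was 1 with the replicate block, a gene outside the 7, and 0 with the luminal covariate, the B lymphocyte covariate, both tissue covariates, the epidermis arrays left out, single probe sets, or only the RonTK-/- arrays.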

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

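The skeletal muscle covariates, the fits without the arrays raised in epidermis genes and the fits on the arrays with or without muscle transcripts alone were chosen after seeing the data, and all other alternatives were planned. The order below is genotype over the 3 ages, at 5, 6 and 7 weeks, interaction, age in RonTK+/+ and age in RonTK-/-, with 11, 2, 3, 6, 0, 19 and 7 genes. All 11 genes over the 3 ages kept their call and sign with array weights, the replicate block, the residual component and each covariate, and 8 did without the epidermis arrays.

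Quantile normalization gave 1, 0, 0, 0, 0, 2 and 2 genes and 0% called near Mst1r (Fisher's exact p = 1), against 1.63%. It stretches arrays of small spread, such as RonTK+/+ array 1 at 5 weeks (SD 0.125), by construction, and whether that ended the calls was not tested. Array weights gave 23, 10, 8, 546, 0, 592 and 5356 genes, with weights from 0.311 (RonTK+/+ array 3 at 7 weeks) to 4.22 (RonTK-/- array 1 at 5 weeks). They were estimated gene by gene because the default estimate did not converge. The residual component gave 16, 10, 346, 85, 737, 689 and 3800 genes. It leaves the log2 differences as they are and removes spread by construction. The luminal covariate gave 13, 3, 3, 6, 0, 0 and 0 genes, the B lymphocyte covariate 15, 8, 4, 9, 0, 23 and 0, the skeletal muscle covariate 15, 6, 3, 7, 0, 192 and 11, and both tissue covariates 15, 2, 4, 6, 0, 62 and 0. Without the epidermis arrays the counts were 9, 2, 2, 3, 0, 3 and 0. Genotype gave 3 genes in the 10 arrays with muscle and 3 in the 8 low in it. Tested singly, probe sets gave 28, 13, 10, 10, 0, 0 and 0. Only the groups compared gave 0, 1 and 3 genes at 5, 6 and 7 weeks and 0 with age in either genotype. At an adjusted p under 0.1 the age counts were 62 and 73, at a fold of at least 2 they were 2 and 0, and genotype over the 3 ages gave 3. Apart from the construction named, the cause was not tested.

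With the replicate block, the counts were 12, 2, 3, 5, 0, 0 and 1 genes. Smad6 and Mid1 lost their calls at 7 weeks with it. Same-number deviations correlated from -0.828 to 0.871, 23 of 45 pairs over 0.1, and 7 of 18 arrays were closest to an array of their own number. No steady likeness by array number was thus seen. With 68.8% of the residual variance on the leading component, these values could miss a weaker tie, so whether array numbers pair the samples stays open.

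Leaving out each array in turn gave 10 to 41 genes over the 3 ages, 2 to 3 at 5 weeks, 3 to 4 at 6 weeks, 3 to 886 at 7 weeks, 0 to 122 for the interaction, 0 to 350 and 0 to 30 with age, and 1.63% to 2.17% near Mst1r. The list counts ran from 6 to 19 over the 3 ages, 12 to 19 at 5 weeks, 8 to 13 at 6 weeks, 6 to 19 at 7 weeks, 12 to 19 with age in RonTK+/+ and 10 to 16 in RonTK-/-. With the estimated correlation they were 0 in all 6 comparisons, and within 5 Mb of Mst1r 0.595% of genes were called (Fisher's exact p = 0.0973).

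Some list calls turned direction. At 6 weeks, both tissue covariates turned the skeletal muscle list (adjusted p = 0.933) and oxidative phosphorylation (adjusted p = 0.849). For skeletal muscle the covariate is that list's own mean, which sets its difference near 0 by construction, so its sign says nothing. At 5 weeks the epidermis list turned without the epidermis arrays (adjusted p = 0.68). Without single arrays, adjusted p ran from 0.00104 to 0.971 for brown adipocyte and 3.72e-05 to 0.691 for epidermis genes at 5 weeks, 9.84e-05 to 0.937 and 5.65e-05 to 0.347 for oxidative phosphorylation at 6 and 7 weeks, and 1.12e-06 to 0.983 for collagen and matrix synthesis with age in RonTK+/+.

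Median centring moved arrays by at most 0.000283 on the log2 scale and changed no count. A filter on dim probe sets, a mean-variance trend and pseudocounts of 1 and 64 were planned but not run, because the ratios hold no absolute level, and the mean of a gene's probe sets became the rule itself. Signal over background, and so what it limits, is unknown.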

Other observations

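The tests of calls kept with tissue covariates, of probe sets and of each side of Mst1r were chosen after the results were seen. So were those of the range of the muscle list and of Zfp949 in RonTK+/+ array 3 at 7 weeks. The genes in the next 2 paragraphs were also chosen after the results were seen.

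RonTK+/+ arrays 1 and 2 at 7 weeks shared a profile that array 3, which lay nearer RonTK-/-, did not. Leaving out such an array enlarges the difference between genotypes. Without array 3, limma named by the same rule Tnfsf11, encoding RANKL (RonTK-/- minus RonTK+/+ -4.19 ± 0.53, adjusted p = 0.0012), the Wnt agonist gene Rspo1 (-3.63 ± 0.28, adjusted p = 4.59e-05), Gjb2 (-2.48 ± 0.38), Wfdc12 (-2.74 ± 0.41), Serpinb11 (-2.90 ± 0.56) and the proliferation gene Mki67 (-2.46 ± 0.46). Higher in RonTK-/- were Lalba (3.88 ± 0.60), Cck (3.95 ± 0.70), the ionocyte regulator gene Foxi1 (3.65 ± 0.48), lactoferrin (Ltf, 3.59 ± 0.63), the fibrinogen gene Fgg (3.57 ± 0.74) and Clic6 (3.38 ± 0.43). Tnfsf11 was 3.17 and 3.21 in arrays 1 and 2, -1.23 in array 3 and -0.998 ± 0.142 (SD, n = 3) in RonTK-/-. Rspo1 was 3.94, 3.55, 0.16 and 0.11 ± 0.25. With all 18 arrays none of these genes passed, with adjusted p from 0.204 for Lalba to 0.507 for Serpinb11 (0.418 for Tnfsf11 and 0.38 for Rspo1).

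Of the circadian clock genes, Nr1d1 was 0.67 ± 0.16 higher in RonTK-/- over the 3 ages (adjusted p = 0.0144 over the list alone, 0.656 over all genes) and 1.31 ± 0.27 higher at 7 weeks (0.00519 and 0.204). Cry1 was -0.61 ± 0.16 at 7 weeks (0.0166 and 0.351). In RonTK-/- from 5 to 7 weeks, the monocyte receptor gene Cd14 rose by 1.00 ± 0.17 (adjusted p = 0.0328), Muc1 by 1.01 ± 0.18 (adjusted p = 0.0361) and Smad6 by 0.84 ± 0.15 (adjusted p = 0.0361) in the contrast of those ages. Cd14, Muc1 and Smad6 were not among the 7 genes called by the moderated F.

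The genotype calls lay almost all on chromosome 9. Tissue content is argued against, since 10 of the 10 chromosome 9 genes stayed called in the same direction with both tissue covariates. A candidate explanation is flanking DNA of the strain used for gene targeting, carried along with the deleted allele. Among genes not called, 6.91% within 20 Mb of Mst1r had an unadjusted p under 0.05, against 3.65% elsewhere (Fisher's exact p = 0.00284). The share was 10.7% on the side of the calls and 4.25% on the other (Fisher's exact p = 0.585 against all other genes). That side was picked by where the calls lay, so the split by side adds no support. All calls on chromosome 9 preceded Mst1r, none nearer than Srprb. Altered probe targets cannot be told apart from altered transcript levels. In 4 of the 7 chromosome 9 genes with several probe sets, all changed in the same direction, each at an unadjusted limma p under 0.05. These were C920006O11Rik, Cep162, Pxylp1 and Zfp949, and of them only Zfp949 had probe sets that changed by like amounts. Srprb, Nck1 and Mapk6 did not meet this. An effect of the missing kinase on these genes stays open and untested, as the deletion and its flanks are inherited together.

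Skeletal muscle and lymphocyte transcripts split the arrays within groups, by up to 5.87 log2 units of the muscle list in RonTK+/+ at 6 weeks, a range that defines the split and tests neither genotype nor age. A candidate explanation is that glands of different body position were taken, as caudal minus rostral genes (Hox, Tbx and Pitx1) changed with the muscle list by -0.193 ± 0.0188 (SE) per log2 unit beside the group means. Their difference lay between 0.81 and 0.98 in the arrays low in muscle and between -0.48 and -0.002 in the others. Hoxc10 carried most of this (-0.626 per unit, limma adjusted p = 5.36e-06), the rostral genes Hoxc4 (0.159) and Hoxa5 (0.135) and the caudal gene Hoxa10 (-0.118) followed, but the caudal genes Tbx4 (0.0861) and Pitx1 (0.0229) went the opposite way, and muscle tissue could itself carry position genes. Of 18193 genes, 5604 varied with the muscle list within groups (limma adjusted p under 0.05). A slope on that list is thus not particular to position genes. The labels do not say which glands were taken, and all RonTK-/- arrays at 6 weeks but none at 7 weeks were low in muscle.

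Cell cycle genes were lower in RonTK-/- at 7 weeks, with RonTK+/+ array 3 at RonTK-/- level. A RonTK-/- sample under that label is argued against by its Zfp949 log2 ratio of 0.088, within -0.33 to 0.52 of the other RonTK+/+ arrays and outside -2.39 to -1.85 of RonTK-/-. Zfp949 was picked from calls made with that label in use, which favours this outcome at 7 weeks. Its values also lay apart between genotypes in all arrays at 5 and 6 weeks, to which that array does not belong. Tissue content as measured by both tissue covariates is argued against, though narrowly, since the cell cycle difference was -0.78 ± 0.35 (SE) with them and -0.83 ± 0.32 without. The stage of the ovarian cycle may differ between animals, but of the progesterone-responsive genes set for the test Calca was not measured and Wnt4 gave 0 genes above all 16 other arrays, with 0.65 as the lower of arrays 1 and 2 and 0.67 as the highest of the others. By their labels RonTK+/+ arrays 1, 2 and 3 share a genotype, so genotype does not account for the split among them. For the difference between genotypes, cycle stage and genotype cannot be told apart here, because the labels give no stage.

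Other splits of the arrays were tested. For genotype over the 3 ages, 1 of 100 splits, the real one itself, gave 11 genes (highest other 1). A count this large was thus rare among the splits. The same holds for age in RonTK-/- (1 of 100, real 7, highest other 2). There all arrays at 6 weeks but none at 7 weeks were low in muscle, so the splits cannot tell age from tissue content. Chance is not excluded for age in RonTK+/+, where 8 of 100 splits gave at least 19 and the highest 2398. For the interaction the real count was 0, so that 100 of 100 splits gave at least as many (highest other 1) was bound to hold and tests nothing. The split with 2398 genes put together RonTK+/+ array 2 of each age, low in muscle. Another set held RonTK+/+ arrays 1 at 6 and 7 weeks and 3 at 7 weeks, low in lymphocytes. The remaining set was mixed, with RonTK+/+ array 3 at 6 weeks, low in muscle, array 3 at 5 weeks, low in lymphocytes, and array 1 at 5 weeks. The split thus followed tissue content only in part. At single ages the 10 splits are too few for a share under 0.05, with real counts of 2, 3 and 6 genes at 5, 6 and 7 weeks (1 split each as large, the real one) and highest others of 0, 0 and 1. For the list counts chance is not excluded over the 3 ages (75 of 100, real 11, highest other 23), with age in RonTK+/+ (21 of 100, real 17, highest other 21) or in RonTK-/- (64 of 100, real 12, highest other 22). At 5, 6 and 7 weeks the real list counts were 15, 9 and 10, with 6, 9 and 7 of 10 splits as large and highest others of 21, 23 and 14.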
